A study of Mus musculus with 31 samples.

How the data were processed

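RNA-seq libraries came from 3 fat depots of male C57BL/6J mice aged 8 weeks: interscapular brown adipose tissue (iBAT), inguinal white adipose tissue (iWAT) and epididymal white adipose tissue (eWAT). Per the labels' protocols, mice were acclimated at thermoneutrality for 8 days and then either killed (day 0) or moved to 4 °C for 2 or 4 days, and 1 µg of total RNA went into each Illumina library. The 31 libraries fall into 9 groups of 3 to 5. Label numbers recur across tissues within a time point and never across time points of 1 tissue.

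The authors deposited 1 table per tissue of raw counts per RefSeq transcript accession. The submitters' processing notes name cutadapt and BWA without versions, and build mm10; the counting step, the annotation release, strand use and duplicate removal are not recorded. Each table holds whole numbers of at least 1 and missing values but no 0, so a missing value was read as a count of 0, as was an accession found in other tables only. In iBAT548 and iBAT539, 57 and 159 features have a count of 1, against 1014 to 1224 in the other iBAT libraries, and 4.39% and 0.7% of genes with a tissue median of 20 to 50 CPM have no count, against 0% in the others. A missing value in these 2 libraries is therefore not shown to be a count of 0. Because strand use is not recorded, reads of overlapping and antisense genes cannot be told apart, and counts of genes with near-identical copies, such as Pgk1, Pgam1, Hba-a1 and Hba-a2, are uncertain. Accessions were matched to symbols and positions in the RefSeq annotation of GRCm38.p6, the assembly that mm10 represents. Of 17334 accessions, 17030 took their symbol from RefSeq, 105 from GENCODE M21, and 199 had none; 937 share a symbol with another accession. Some genes and list members have no row in the tables used and were not analysed here.

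Total counts per library ran from 1.58 to 3.76 in iBAT (median 2.78), 1.5 to 5.53 in iWAT (3.42) and 3.19 to 4.03 in eWAT (3.88), in M. PCR duplicates were not marked by molecular identifiers, so counting error alone understates the spread; chi-square per degree of freedom between replicate libraries ran from 11.8 to 186.7. The common biological coefficient of variation was 0.55 in iBAT, 0.538 in iWAT and 0.583 in eWAT.

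Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr (minimum count 10, minimum total 15), 1 mean per time point within a tissue, robust quasi-likelihood F-tests (two-sided), and Benjamini-Hochberg adjustment within each comparison with a threshold of 0.05. This left 8270 genes in iBAT, 9574 in iWAT and 10043 in eWAT. Depots were compared at day 0, and in their day 4 change, in 1 fit of all 31 libraries over 10681 genes. Each standard error (SE) is the absolute log2 change divided by the square root of its F, and log2 CPM for the library score used a prior count of 2. Levels are CPM (counts scaled to a fixed library total) on TMM-scaled library sizes, given as mean ± SD over libraries; summed marker levels are CPM of the plain total count over all members of a list.

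Before the data were examined, the comparisons, tests, alternatives, 18 fixed genes and 32 gene lists were written down: 22 lists of pathways and adipocyte programmes, 9 of markers of other cell types, and 1 of immediate early genes as a sign of tissue handling. Of the fixed genes, 15 have a row in the tables used. Lists were tested with camera (limma 3.58.1) on voom log2 CPM at a preset correlation of 0.01, adjusted over all lists and the 6 comparisons against day 0, and again with the correlation estimated from the libraries; a list needed at least 2 tested members. Members were also counted past 0.05 over all genes and adjusted over the list alone. The rule for named genes took (a) the fixed genes, (b) the 5 largest rises and the 5 largest falls past the threshold with at least 5 CPM in a group and no overlap between libraries of the groups (at day 0 between depots, without the overlap condition), and (c) up to 3 members of each list past the threshold and 1 that was not. Other names were chosen after their values were seen; these are the list members past 0.05 only over the list alone, and Ankrd9, Ctsz, Cars2, Rom1 and Tesc.

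Within groups, libraries spread along 1 axis shared by all tissues. After the data were seen, each library was given a score: the projection of its deviations on the within-group axis found in the other 2 tissues. These deviations were taken from the mean of all libraries of its tissue over all time points. The score can therefore differ between days as well as within groups, and a fit with it can take up part of a difference between days. Scores fell on a high and a low side of a gap. Fits with the score as a covariate, and fits on 1 side of the gap with at least 2 libraries per group, are given beside the main results. Alternative settings written beforehand were RLE size factors, library size alone, no filter, DESeq2 1.42.0, limma voom, fits on only the compared groups, the label number as a block across tissues, and leaving out each library. Added after seeing the data were the score fits, and fits without 2 iBAT libraries with few detected features, without the iBAT library with most muscle marker counts, and without 5 libraries high in epididymis and testis markers. Other splits of the same libraries were refitted, up to 100 per result and 30 for differences in day 4 change.

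The fits listed here were tested on simulated counts drawn with the means, dispersions and library sizes of the real libraries and 200 changed genes. For iBAT at day 2 against day 0 (8005 genes), edgeR recovered 21% of genes changed 4-fold and 78% of those changed 16-fold, with 3 false calls; DESeq2 recovered 53% and 86% with 40 false calls. For iBAT at day 4 (8021 genes) edgeR recovered 11% and 77% with 10 false calls. In iWAT the shares were 24% and 84% at day 2 (9394 genes) and 42% and 94% at day 4 (9401 genes). In eWAT they were 10% and 63% at day 2 (9797 genes) and 10% and 70% at day 4 (9792 genes). For the difference in day 4 change between iBAT and iWAT (10473 genes) they were 8% and 55%. False edgeR calls there numbered 4, 3, 0, 1 and 3. DESeq2 made 41 false calls in iBAT at day 4, 38 and 21 in iWAT at days 2 and 4, and 41 and 36 in eWAT. Real DESeq2 counts can hold false calls too, but the simulated numbers do not carry over directly. In eWAT the real DESeq2 counts at days 2 and 4 were 0 and 4, below the simulated false calls. A library axis was also laid over the simulated counts at day 2. Its values were drawn without regard to day, and the dispersions were set below the real ones. A score that goes with the day, as in iWAT at day 2, was therefore not simulated. With this axis the score fit recovered 64% and 95% with 17 false calls in iBAT, against 32% and 83% with 1 without the score. In iWAT it recovered 63% and 96% with 7 false calls, against 46% and 91% with 1, and in eWAT 39% and 92% with 2, against 37% and 93% with 3. Camera at the preset correlation recovered 10 of 10 lists of 20 genes raised 2-fold in each tissue at day 2. It called 1, 1 and 0 of 200 unchanged lists. With an estimated correlation it recovered 10, 10 and 5 of 10 in iBAT, iWAT and eWAT and called 0 unchanged lists. Both used counts simulated gene by gene without correlation. False calls among real lists, whose members can vary together, were therefore not measured. Day 4 against day 2, the replicate block, other pairs of depots, and camera and the score at day 4 were not simulated. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.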

Results

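Gene expression was measured by RNA-seq in 3 fat depots of mice kept at thermoneutrality (day 0) or moved to 4 °C for 2 or 4 days. The depots were interscapular brown fat (iBAT), whose adipocytes burn fuel for heat, inguinal white fat (iWAT), which can acquire heat-producing cells in the cold, and epididymal white fat (eWAT). There were 3, 4 and 3 libraries of iBAT at days 0, 2 and 4, then 4, 3 and 5 of iWAT, and 3, 3 and 3 of eWAT. Libraries are named by depot and label number. Total counts, in M, are given for each. In iBAT they were 2.71, 3.75 and 3.76 at day 0 (iBAT516, iBAT517 and iBAT518). At day 2 they were 1.58, 2.55, 2.99 and 1.73 (iBAT532, iBAT534, iBAT535 and iBAT539), and at day 4 they were 3.42, 2.2 and 2.85 (iBAT548, iBAT550 and iBAT555). In iWAT they were 3.42, 3.42, 1.51 and 2.83 at day 0 (iWAT516, iWAT517, iWAT518 and iWAT522) and 3.54, 3.46 and 3.64 at day 2 (iWAT532, iWAT538 and iWAT539). Day 4 of iWAT had 3.3, 4.76, 1.6, 1.5 and 5.53 (iWAT548, iWAT550, iWAT551, iWAT553 and iWAT555). In eWAT they were 3.94, 4.03 and 3.42 at day 0 (eWAT516, eWAT517 and eWAT518), 3.38, 3.19 and 3.88 at day 2 (eWAT532, eWAT538 and eWAT539), and 4.03, 4.01 and 3.86 at day 4 (eWAT548, eWAT551 and eWAT553). Features with counts ranged from 7535 to 11875 in iBAT, where iBAT548 (7535) and iBAT539 (8698) had fewest. They ranged from 10820 to 14771 in iWAT and from 12573 to 13517 in eWAT.

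Replicates of a group differed along an axis shared by all 3 depots, with the keratin gene Krt17, Ddt and the respiratory chain gene Cox8b at the high end and Sema4b and Id3 at the low end. This axis held 54.2% of the within-group variance in iBAT, 43.7% in iWAT and 53.5% in eWAT, and the genes' loadings correlated between depots with r from 0.662 to 0.784 across 7938 genes, which are not independent replicates. Libraries with a high score were iBAT535 and iBAT539 (day 2) and iBAT548 (day 4) in iBAT, and eWAT518 (day 0), eWAT532 and eWAT538 (day 2) in eWAT. In iWAT they were iWAT516, iWAT517 and iWAT518 (day 0) and iWAT550, iWAT551 and iWAT553 (day 4), so that all 3 day 2 libraries lay on the low side. Gene counts with the score as a covariate stand beside the gene counts below, and counts of lists with the score, or on 1 side of the gap, beside some. Adjusted p values from these fits stand beside the lists whose call they changed. For members past the test over a list alone they are given for some lists only. In iWAT and eWAT at day 2 too few libraries lay on the same side as the day 0 libraries for a fit on 1 side.

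**Figure D1:**
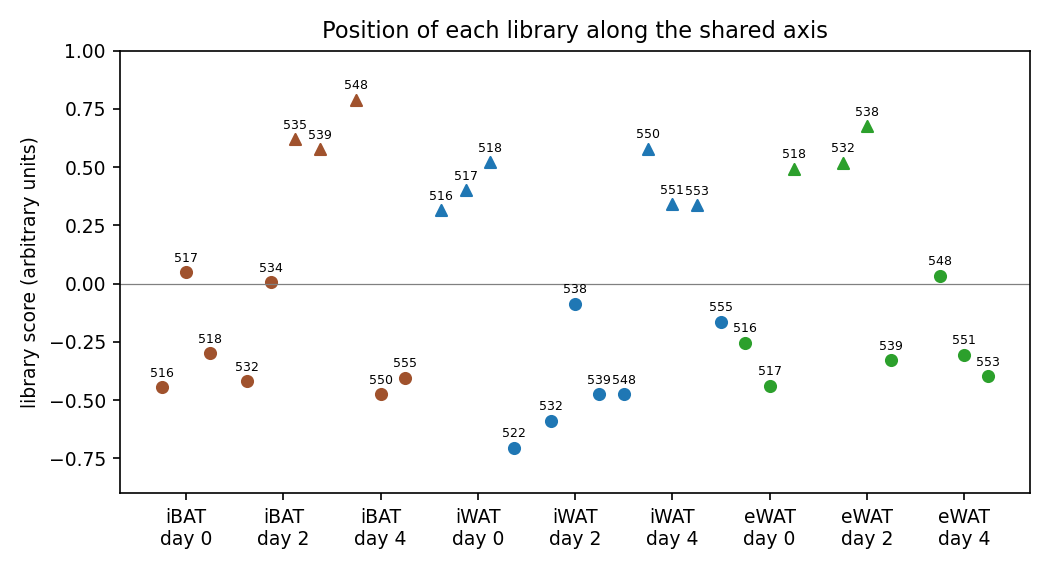
Library score (no unit) of each of the 31 libraries by depot and day in the cold, with triangles for libraries on the high side of the gap. All 3 iWAT day 2 libraries lie on the low side, while 3 of the 4 iWAT day 0 libraries lie on the high side.

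The depots were first compared at thermoneutrality, the baseline for their cold responses. Brown fat had far more transcript for the machinery of heat production. Ucp1, the uncoupling protein that lets protons re-enter mitochondria without making ATP, Cidea, a lipid droplet protein of brown adipocytes, and Pdk4, a kinase that holds back pyruvate oxidation, were higher in iBAT than in both white depots. iWAT was in turn above eWAT for Ucp1, Cidea and Pdk4. Lymphocyte markers stood out in iWAT, and leptin (Lep), the hormone that reports fat stores, was lower in iBAT than in eWAT. Ucp1 was higher in iBAT than in iWAT by a log2 difference of 5.14 (SE 1.04, adjusted p = 8.86e-04) and than in eWAT by 9.85 (SE 1.45, adjusted p = 5.44e-05). iWAT exceeded eWAT in Ucp1 by 4.71 (SE 1.15, adjusted p = 0.00959). Cidea differed by 4.47 (SE 0.68), 9.29 (SE 0.99) and 4.82 (SE 0.85) in the same 3 comparisons, and Pdk4 by 4.39 (SE 0.66), 7.03 (SE 0.84) and 2.64 (SE 0.67). Lep was lower in iBAT than in eWAT, with a log2 difference of -3.00 (SE 0.87, adjusted p = 0.0266), a call lost in 4 of 6 fits with 1 library left out. The glucose transporter gene Slc2a1 was lower in iBAT than in iWAT, with -1.83 (SE 0.45, adjusted p = 0.00525).

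Of 18 thermogenic and brown adipocyte genes, 14 were higher in iBAT than in iWAT over all genes (15 adjusted over the list alone; median log2 difference 3.08), 15 higher than in eWAT (16 over the list alone; 4.563), and 7 higher in iWAT than in eWAT (8 over the list alone; 2.04). The nuclear-encoded respiratory chain followed brown fat as well, with 37 of 49 genes higher in iBAT than in iWAT (40 over the list alone; 2.06) and 36 higher than in eWAT (44 over the list alone), against 0 of 49 between iWAT and eWAT. Fatty acid oxidation genes were higher in iBAT than in iWAT for 10 of 20 (13 over the list alone) and than in eWAT for 14 (16 over the list alone), and genes of the tricarboxylic acid cycle for 11 and 10 of 16. Genes of the cyclic AMP and adrenergic response, which carries the sympathetic signal, were higher in iBAT than in either white depot for 7 of 9.

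Markers of other cell types also differed between depots at day 0. All 12 lymphocyte markers tested, which include the B cell gene Ms4a1, were higher in iWAT than in iBAT and than in eWAT. Their summed level was 3201 ± 706 CPM (SD, n = 4) in iWAT. Ccl19 and Marco, at 196.7 ± 191.6 and 207.8 ± 181.9 CPM in iWAT, were among the 5 largest differences above iBAT. Cell cycle genes were higher in iWAT than in iBAT for 11 of 21 and than in eWAT for 6 of 21. Whether these iWAT transcripts came from the fat or from other tissue dissected with the pads was not tested. Skeletal muscle markers were higher in iBAT than in iWAT for 15 of 16 and than in eWAT for 14 of 16, and the slow muscle genes Myl2 and Myh7 were among the 5 largest differences against each white depot. Summed muscle markers reached 36070 ± 23990 CPM (n = 3) in iBAT and 1584 ± 1748 CPM (n = 4) in iWAT. Sperm and epididymis genes varied between single white libraries: Tnp1, Tnp2 and Prm1 were higher in iWAT than in iBAT (Prm1 not with the score, adjusted p = 0.0514), with 937.6 CPM of such markers in iWAT522 and at most 111.2 CPM in the other 3. Spink8, Akr1b7, Wfdc13 and Spink11, which are epididymis or vas deferens genes, were higher in eWAT than in iBAT. Akr1b7 alone averaged 4139 ± 7160 CPM in eWAT, an SD above its mean. The epididymis and testis marker list, which does not hold all of these genes, summed to 1298 ± 1572 CPM (n = 3) in eWAT at day 0.

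In edgeR, 1926 genes differed between iBAT and iWAT at day 0 (892 higher in iBAT), 1029 between iBAT and eWAT (537 higher in iBAT) and 808 between iWAT and eWAT (286 higher in eWAT). With the library score as a covariate, 1181 were higher in iBAT and 1207 in iWAT, and 795 in iBAT and 745 in eWAT. The score is centred within each depot, so fits with it do not adjust for a difference in score level between depots. At day 0 all iBAT libraries lay on the low side and most iWAT libraries on the high side, so depot and side are close to confounded. Between iWAT and eWAT 1302 differed with the score, 747 of them higher in iWAT, and the count higher in eWAT moved by over 1.5 times. With the score and the label number as a block, 586 were higher in iBAT and 808 in iWAT, 646 in iBAT and 694 in eWAT, and 554 in iWAT and 310 in eWAT. In DESeq2, 936 were higher in iBAT and 1721 in iWAT, 637 in iBAT and 879 in eWAT, and 805 in iWAT and 456 in eWAT. With RLE factors 504 were higher in iBAT and 566 in eWAT, so which of these 2 depots had more genes higher turned with the setting. Single libraries moved some counts by over 1.5 times: 1926 fell to 1179 without iBAT516 and 1191 without iBAT518. The 1029 fell to 576, 569 and 601 without iBAT516, iBAT517 and iBAT518 and to 603 without eWAT516. The 808 became 380 without eWAT516, 508 without eWAT517, 509 without iWAT516 and 1225 without iWAT522.

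What 2 days of cold did to brown fat was the next comparison. Genes that rose include Ckb, a creatine kinase, Elovl3, an elongase of very long chain fatty acids induced by cold, Dio2, which activates thyroid hormone inside the cell, and Acot11, an acyl-CoA thioesterase of brown fat. Hcn2, a channel subunit for pacemaker currents, and Sgk2, a serum and glucocorticoid regulated kinase, rose with them. Svep1, an extracellular matrix protein, and Impdh1, an enzyme of guanine nucleotide synthesis, fell. Ckb (NM_021273, GRCm38 chromosome 12, 111669355 to 111672338) rose from 54.4 ± 20.6 CPM (SD, n = 3) to 1091 ± 555.2 CPM (n = 4), a log2 change of 4.33 (SE 0.56, adjusted p = 0.0257). Elovl3 (NM_007703, chromosome 19, 46131897 to 46135694) rose from 47.5 ± 31.2 to 629 ± 236 CPM, by 3.73 (SE 0.58), and Dio2 (NM_010050, chromosome 12, 90724552 to 90739038) from 32.1 ± 23.0 to 349 ± 86.7 CPM, by 3.44 (SE 0.56). Both had an adjusted p of 0.0389. Acot11 (NM_025590, chromosome 4, 106744555 to 106805007) rose by 2.51 (SE 0.40), Hcn2 (NM_008226) by 4.06 (SE 0.67) and Sgk2 (NM_013731) by 3.67 (SE 0.59). Svep1 (NM_022814, chromosome 4, 58042796 to 58206596) went from 79.7 ± 26.2 to 10.1 ± 1.04 CPM, a log2 change of -2.97 (SE 0.39, adjusted p = 0.0257), and Impdh1 (NM_011829) from 424 ± 223 to 54.5 ± 13.3 CPM, -2.96 (SE 0.48). For each of these genes all 4 day 2 libraries lay beyond all 3 day 0 libraries, which the rule for naming the largest changes requires.

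These were 8 of the 13 genes past the threshold in edgeR, 11 higher and 2 lower. The others, Ankrd9, Ctsz, Cars2, Rom1 and Tesc, named after their values were seen, rose by 2.33 to 3.10. DESeq2 called 185 genes higher and 121 lower, all 13 among them, voom 11 and 2, and the score fit 37 and 10, again with all 13. On the low side of the score gap alone 46 and 7 were called. The 13 calls depended on single libraries: 0 were called in fits without any 1 of iBAT516, iBAT517 and iBAT518 or iBAT535 and iBAT539, 1 without iBAT534 and 3 without iBAT532, while Ckb kept log2 changes between 3.96 and 4.67 in these fits. Scaling by library size alone shifted the median gene by -0.28 and left 1 call, Svep1. Of 13 fixed genes tested, 2 rose. Ucp1, at 5889 ± 1742 CPM before and 18010 ± 12390 CPM after, had a log2 change of 1.61 (SE 0.56, adjusted p = 0.277), or 1.96 with the score.

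**Figure D2:**
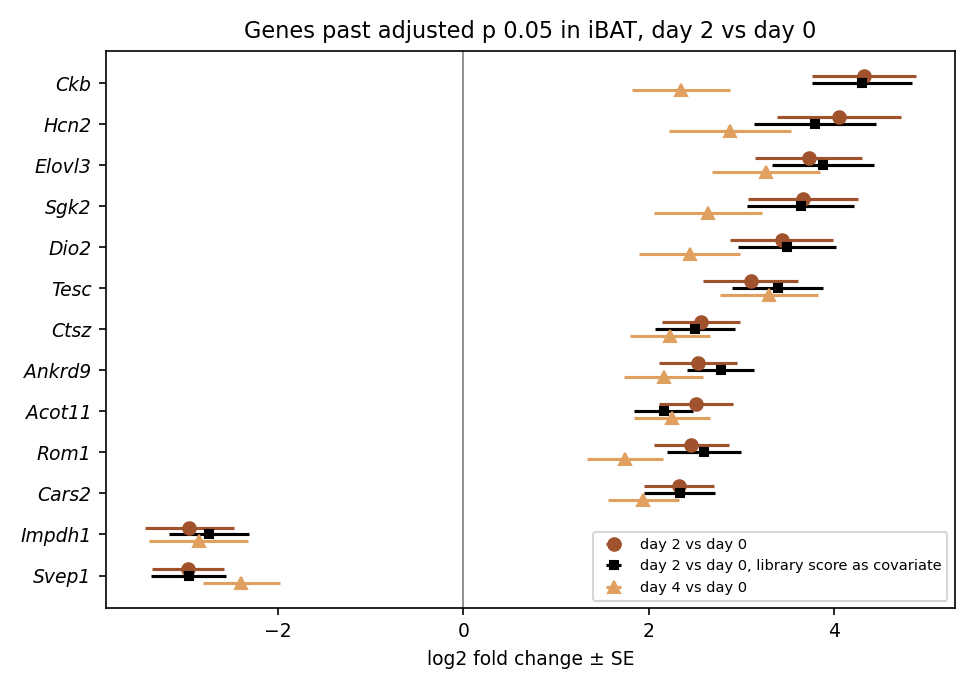
Log2 change (bars, SE) of the 13 genes past the threshold in iBAT at day 2 against day 0, at day 2 with the library score as a covariate, and at day 4 against day 0. Ckb stands at 4.33 at day 2 and 2.35 at day 4.

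Among gene lists in brown fat at day 2, camera at the preset correlation passed 11 as higher and 2 as lower, and 0 with an estimated correlation. In parentheses after a list are, in order, the members with a change in its direction, the median log2 change and the camera adjusted p. Thermogenic genes rose as a list. In it, 16 of 20 had positive log2 changes (median 1.43), 3 rose over all genes and 9 adjusted over the list alone, with a camera adjusted p of 9.99e-09 (adjusted p = 0.0526 with an estimated correlation). Beyond Elovl3, Dio2 and Acot11, those adjusted over the list alone include Bmp8b, a secreted factor that sharpens the response to sympathetic input (3.55, SE 0.73), the potassium channel gene Kcnk3 (1.72, SE 0.41) and Ucp1 (list-alone adjusted p = 0.0320, higher than every day 0 library in 3 of 4). All 20 fatty acid oxidation genes had positive changes (median 0.86), 4 of them past the test over the list alone. Among these were Acsl5, which charges fatty acids with coenzyme A (3.34, SE 0.65), and the carnitine carrier gene Slc25a20 (1.61, SE 0.38). Camera gave an adjusted p of 4.83e-07 (adjusted p = 0.0748 with an estimated correlation). Glycolysis and glucose uptake rose too, with 12 of 12 positive (median 1.33), 3 past the test over the list alone, namely Pgk1 (2.15), Pgam1 (2.22) and Slc2a4, the insulin-dependent glucose transporter (1.73, SE 0.45). The list's camera adjusted p was 2.55e-04 (adjusted p = 0.251 with an estimated correlation), and 8 members passed with the score. Pyruvate entry into mitochondria had 10 of 12 positive (median 0.90), with the carrier gene Mpc1 (2.48, SE 0.75) and Dlat of the pyruvate dehydrogenase complex (1.14, SE 0.34) past the test over the list alone, at a camera adjusted p of 0.00314 (adjusted p = 0.178 with an estimated correlation).

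Mitochondrial and lipid synthesis lists also passed in iBAT at day 2. The tricarboxylic acid cycle had 14 of 16 genes positive (median 0.76, camera adjusted p = 0.00105, adjusted p = 0.251 with an estimated correlation). The nuclear-encoded respiratory chain had 38 of 49 (median 0.47, camera adjusted p = 5.14e-04, adjusted p = 0.305 with an estimated correlation), in each case with 0 genes past the test on its own. Lipid synthesis lists that passed were de novo lipogenesis (10 of 12 positive, median 0.60, adjusted p = 0.0296, adjusted p = 0.484 with an estimated correlation) and triglyceride synthesis (8 of 8, 0.65, 0.0120, adjusted p = 0.184 with an estimated correlation). Sterol biosynthesis passed as well (12 of 17, 0.69, 0.0162, adjusted p = 0.184 with an estimated correlation). In the sterol list 5 genes rose over the list alone, among them Sc5d (1.28, SE 0.35), and Fdft1, squalene synthase, fell (-1.79, SE 0.41). Peroxisomal genes (13 of 16 positive, 0.65, adjusted p = 0.00867, adjusted p = 0.178 with an estimated correlation) and the pentose phosphate pathway (6 of 7, 0.69, 0.0300, adjusted p = 0.250 with an estimated correlation), with G6pdx, its first enzyme, at 2.51 (SE 0.69), completed the 11 lists that rose. With the score G6pdx and Pgd did not pass over the list alone (each 0.0621), while 3 genes of triglyceride synthesis in place of 0 and 3 peroxisomal genes in place of 1 did. Single libraries ended 3 of these calls: lipogenesis without iBAT534 (adjusted p = 0.131) or iBAT535 (0.0643), triglyceride synthesis without iBAT532 (0.0571), and the pentose phosphate pathway without iBAT539 (0.0651), or on the low side of the score gap (0.117).

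Immediate early genes, which respond within minutes to stress and handling, fell in iBAT at day 2. Of these, 11 of 12 had negative changes (median -1.39), and 6 fell over the list alone, among them Fos (-2.42, SE 0.49), Egr1 (-2.84, SE 0.81) and Jun (-1.67, SE 0.39), with a camera adjusted p of 4.83e-07 (adjusted p = 0.251 with an estimated correlation). Skeletal muscle markers fell with them, 17 of 17 negative (median -1.91) and 9 past the test over the list alone, including Acta1 (-1.95, SE 0.57), Mylpf (-2.26, SE 0.56) and Casq1 (-2.78, SE 0.57), at a camera adjusted p of 1.42e-07 (adjusted p = 0.304 with an estimated correlation). Their sum was 36070 ± 23990 CPM at day 0, with 63660 in iBAT518, and 10360 ± 2146 CPM at day 2. With the score as a covariate 12 lists rose and 2 fell. The glycogen list did not pass (median 0.23, adjusted p = 0.393, adjusted p = 0.492 with an estimated correlation), and its members went both ways. Pygm, the muscle glycogen phosphorylase, and Phkg1, a muscle phosphorylase kinase subunit, fell over the glycogen list alone (-3.22, SE 0.71, and -2.27, SE 0.70) while Gys2 (3.04, SE 0.57) and Gbe1 (1.20, SE 0.37) rose.

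Lists that did not pass in iBAT at day 2 still held single members past the test over the list alone. The creatine and calcium cycling list, with Ckb and Alpl (1.92, SE 0.53) higher, had a median of -0.48 but a mean of 0.67 (camera adjusted p = 0.334, direction up). Glycerol metabolism, with Gpd1 at 1.90 (SE 0.40), had a median of -0.25 and a mean of 0.18 (0.849, up), and clock genes, with Nfil3 at 1.49 (SE 0.38), a median of -0.13 and a mean of 0.12 (0.987, down). In the cyclic AMP list (median -0.11, adjusted p = 0.416), Nr4a1 (-2.75, SE 0.52) and Rgs2 fell and Adra1a rose. Lpl, which frees fatty acids from circulating lipoproteins (1.60, SE 0.40), Fabp4 and Fabp5 rose and Apoe fell (-0.88, SE 0.31) in the uptake list (0.14, 0.356). Plin2, a lipid droplet coat protein (2.01, SE 0.49), and Abhd5 rose in the lipolysis list (0.16, 0.154), which passed with the score (0.0193). Loxl1 (2.86, SE 0.57) rose in the fibroblast list (0.22, 0.443), and in the endothelial list (-0.41, 0.617) Vwf rose (2.41, SE 0.75; not with the score, 1.63, SE 0.68, list-alone adjusted p = 0.178) and Cldn5 fell (-1.21, SE 0.35). The medians of the glycogen, lipolysis, uptake, secreted factor and fibroblast lists turned negative when only library size scaled the counts.

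**Figure D3:**
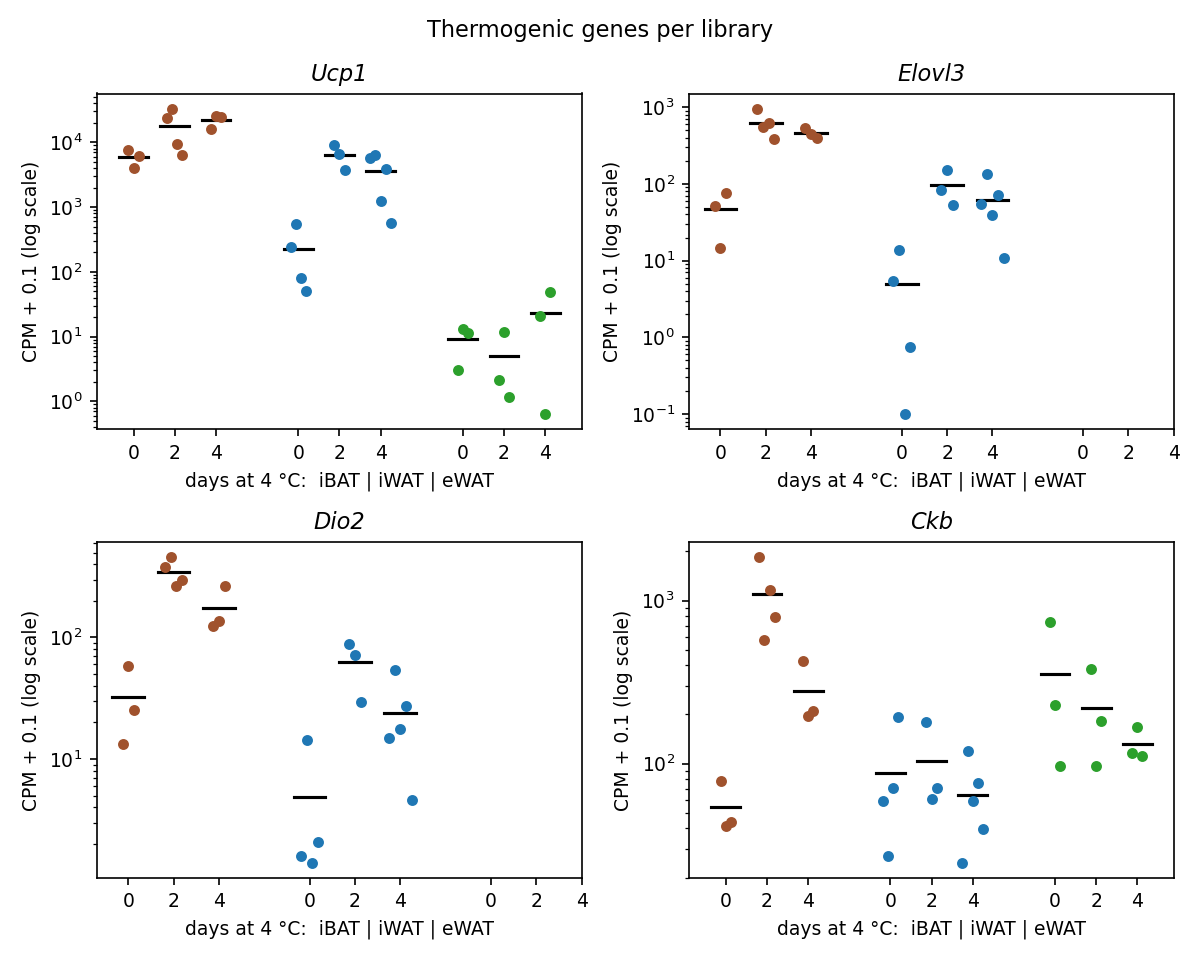
Ucp1, Elovl3, Dio2 and Ckb in each library (CPM plus 0.1, log axis) by depot and day, with lines at group means, and no eWAT points for Elovl3 and Dio2, which were below the filter there. In iBAT, Ckb averaged 54.4 CPM at day 0 and 1091 CPM at day 2.

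At day 4 in brown fat camera at the preset correlation passed 11 lists as higher and 2 as lower, and 0 with an estimated correlation, while no single gene passed over all genes. Elovl3, Dio2 and Ucp1 rose over the thermogenic list alone, and Fos, Btg2 and Egr1 fell over the immediate early list alone. Ucp1 stood at 22120 ± 5387 CPM (n = 3), a log2 change of 1.91 (SE 0.59, list-alone adjusted p = 0.0187), above every day 0 library in 3 of 3. Elovl3 changed by 3.27 (SE 0.58, list-alone adjusted p = 0.00133), Dio2 by 2.44 (SE 0.55, 0.00503) and Ckb, in the creatine list, by 2.35 (SE 0.53, 0.00404). Thermogenic genes had 17 of 20 positive (median 1.29), 9 past the test over the list alone, with a camera adjusted p of 8.43e-08 (adjusted p = 0.0526 with an estimated correlation). De novo lipogenesis, the making of fatty acids from sugar, had 12 of 12 positive (median 0.92, adjusted p = 1.90e-05, adjusted p = 0.251 with an estimated correlation). The fatty acid synthase gene Fasn stood at 12880 ± 1994 CPM against 4539 ± 413 CPM at day 0, a log2 change of 1.51 (SE 0.44) that did not pass.

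Fuel oxidation lists also passed in iBAT at day 4. Fatty acid oxidation had 18 of 20 positive (median 0.73, adjusted p = 2.49e-05, adjusted p = 0.136 with an estimated correlation). Of its members, Slc25a20 and Acsl5 (2.62, SE 0.65) passed the test over the list alone. The respiratory chain had 45 of 49 positive (0.46, 8.17e-06, adjusted p = 0.251 with an estimated correlation) and the tricarboxylic acid cycle 14 of 16 (0.63, 0.00296, adjusted p = 0.266 with an estimated correlation). Glycolysis had 11 of 12 (0.82, 7.19e-04, adjusted p = 0.251 with an estimated correlation) and pyruvate entry 9 of 12 (0.90, 0.00155, adjusted p = 0.178 with an estimated correlation). The pentose phosphate pathway (6 of 7, 0.69, 0.00698), triglyceride synthesis (7 of 8, 0.72, 0.00777) and peroxisomal genes (11 of 16, 0.57, 0.00867) each had an adjusted p = 0.178 with an estimated correlation, and lipolysis (7 of 9, 0.56, 0.0403) an adjusted p = 0.266 with an estimated correlation. Sterol biosynthesis did not pass (11 of 17 positive, 0.43, 0.0714, adjusted p = 0.251 with an estimated correlation), but did with the score (0.00926) and on the low side of the gap (0.0201). With the score, members past the test over the list alone went from 0 to 5 in glycolysis, 4 in pyruvate entry, 3 in triglyceride synthesis, 2 in sterol biosynthesis and 1 in lipogenesis, from 2 to 4 in muscle markers and from 1 up and 1 down to 2 and 2 in the glycogen list. Immediate early genes had 12 of 12 negative (median -1.89, adjusted p = 9.93e-08, adjusted p = 0.251 with an estimated correlation), with Fos at -2.84 (SE 0.55), Btg2 at -2.84 (SE 0.57) and Egr1 at -3.27 (SE 0.92). Skeletal muscle markers had 16 of 17 negative (median -0.99, adjusted p = 5.58e-05, adjusted p = 0.415 with an estimated correlation). Their sum was 15020 ± 10120 CPM. Lipolysis did not pass without iBAT517 (adjusted p = 0.163) or iBAT550 (0.123) or iBAT555 (0.212), muscle markers (0.0704) and triglyceride synthesis (0.0504) without iBAT555, and peroxisomal genes without iBAT548 (0.0588) or on the low side of the score gap (0.0780).

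For single genes at day 4, edgeR called 0 of 8270, with 581 at an unadjusted p under 0.05, where 414 would arise by chance. DESeq2 called 56 higher and 27 lower, and voom 0. With the score as a covariate 14 were higher and 5 lower, among them Elovl3 (3.41, adjusted p = 0.0404). Between days 2 and 4, edgeR called 0 genes. At an unadjusted p under 0.05 there were 263, fewer than the 414 that would arise by chance. DESeq2, voom and the score fit called 0 each.

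Cold exposure of inguinal fat asks whether white fat takes on brown features. Beige adipocyte genes did not pass, with a median of 0.11 at day 2 (adjusted p = 0.827, adjusted p = 0.890 with an estimated correlation) and 0.29 at day 4 (0.937, adjusted p = 0.963 with an estimated correlation), and 0 of 6 members, among them Tmem26 and Tbx1, past the test over the list alone. At day 2 Ucp1 and its companions Elovl3, Dio2 and Cidea rose over the thermogenic list alone. By camera at the preset correlation mitochondrial lists were higher and fibroblast, nerve and muscle marker lists lower. With an estimated correlation these lists did not pass. Ucp1 (NM_009463, chromosome 8, 83290348 to 83298456) went from 229 ± 224 CPM (n = 4) to 6465 ± 2704 CPM (n = 3), a log2 change of 4.82 (SE 0.94, list-alone adjusted p = 0.00212), above every day 0 library in 3 of 3. Over all genes its adjusted p was 0.247. Elovl3 changed by 4.19 (SE 0.98), Dio2 by 3.65 (SE 0.88) and Cidea by 2.85 (SE 0.71), each past the test over the list alone. Thermogenic genes had 15 of 16 positive (median 1.71, or 2.48 with the score), 9 past the test over the list alone and 0 over all genes, at a camera adjusted p of 2.24e-10 (adjusted p = 0.243 with an estimated correlation). The respiratory chain had 44 of 49 positive (median 1.04), with cytochrome c, Cycs, at 2.06 (SE 0.49), and an adjusted p of 1.52e-10 (adjusted p = 0.266 with an estimated correlation). In the tricarboxylic acid cycle 13 of 16 were positive (median 0.64). Over the list alone 5 rose, among them Suclg1 (1.89, SE 0.52), which encodes a subunit of succinate-CoA ligase, at an adjusted p of 2.18e-04 (adjusted p = 0.341 with an estimated correlation).

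Fuel handling in iWAT at day 2 followed. Fatty acid oxidation had 17 of 20 positive (median 0.96, adjusted p = 2.52e-04, adjusted p = 0.395 with an estimated correlation). Glycolysis had 11 of 13 (0.69, 0.00542, adjusted p = 0.304 with an estimated correlation), with the hexokinase gene Hk2 (2.36, SE 0.60) and Ldhb (1.99, SE 0.52) past the test over the list alone. Pyruvate entry had 8 of 12 (0.92, 0.00677, adjusted p = 0.402 with an estimated correlation), with Pdk4, which restrains pyruvate oxidation (2.02, SE 0.58; 1.74, SE 0.59, list-alone adjusted p = 0.0517 with the score), and Pdhx. De novo lipogenesis (11 of 12, 0.41, 0.00547, adjusted p = 0.427 with an estimated correlation) and triglyceride synthesis (8 of 9, 0.39, 0.0195, adjusted p = 0.419 with an estimated correlation) also passed. So did peroxisomal genes (11 of 16, 0.56, 0.0300, adjusted p = 0.490 with an estimated correlation) and sterol biosynthesis (11 of 18, 0.17, 0.0486, adjusted p = 0.341 with an estimated correlation), where Hmgcs1 rose by 1.96 (SE 0.42). With the score, members past the test over the list alone went from 0 to 11 up and 1 down in fatty acid oxidation, 0 to 1 in triglyceride synthesis, 5 to 10 in the tricarboxylic acid cycle, 1 to 9 in the respiratory chain and 1 to 3 in epithelial markers. Outside passing lists, Ppp1r3b, a glycogen targeting subunit (3.44, SE 0.73), Gpd1 (1.81, SE 0.47), Fabp3 (3.83, SE 0.87) and Pgd (1.54, SE 0.39) rose over their list alone. Single libraries ended several calls: lipogenesis (adjusted p = 0.0529), sterol (0.121) and triglyceride synthesis (0.0551) without iWAT516. Without iWAT522, pyruvate entry (0.0599), sterol (0.243) and peroxisomal genes (0.0879) did not pass, nor did peroxisomal genes without iWAT517 (0.0809). Without iWAT532, glycolysis (0.0718), triglyceride synthesis (0.0677) and peroxisomal genes (0.131) did not pass, nor did sterol biosynthesis without iWAT538 (0.0864).

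Of the 9 cell type lists, camera at the preset correlation passed 4 as lower in iWAT at day 2 (fibroblast, nerve, epithelial and muscle markers), and 0 with an estimated correlation. Macrophage (adjusted p = 0.186), lymphocyte (0.854), endothelial (0.970), epididymis (0.208) and blood markers (0.666) did not pass; with the score, epididymis markers passed as lower (median -6.22, 0.00502). Fibroblast markers had 9 of 11 negative (median -1.13), with the collagen gene Col3a1 (-2.53, SE 0.61), Lum (-2.27, SE 0.52) and Fbln1 (-3.67, SE 1.01) past the test over the list alone, at an adjusted p of 5.14e-04 (adjusted p = 0.178 with an estimated correlation; 0.0674 without iWAT522). Nerve and Schwann cell markers had 4 of 4 negative and an adjusted p of 0.00342 (adjusted p = 0.178 with an estimated correlation). Epithelial markers (4 of 4 negative, 0.0497, adjusted p = 0.427 with an estimated correlation) did not pass without iWAT517 (0.145) or iWAT522 (0.264), nor with library size alone (0.0762). Skeletal muscle markers were lower for 15 of 15, 12 of them past the test over the list alone (adjusted p = 8.17e-06, adjusted p = 0.385 with an estimated correlation). Their sum was 1584 ± 1748 CPM at day 0, with 3913 in iWAT517, and 65.6 ± 30.9 CPM at day 2. The secreted factor list had a median of -0.18 with the test direction up (adjusted p = 0.970), and S100a8, a neutrophil gene, rose over the blood list alone (3.12, SE 0.78).

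Over all 9574 genes, edgeR called 0 in iWAT at day 2, with 1020 at an unadjusted p under 0.05, where 479 would arise by chance. DESeq2 called 54 higher and 57 lower, voom 0 and the score fit 0. Without iWAT522 and iWAT555, the libraries high in epididymis and testis markers, edgeR called 66 (50 higher). Without iWAT522 alone it called 0. Once iWAT522 is left out, all day 0 libraries lie on the high side of the score gap and all day 2 libraries on the low side. Day and score side are then fully confounded, so the 66 calls cannot be assigned to the cold. Camera passed 14 lists at the preset correlation, 10 up and 4 down, and 0 with an estimated correlation. At the preset correlation it passed 9 without iWAT522 and iWAT555 and 9 without iWAT522 alone. With the score it passed 16, 11 up and 5 down, which added the pentose phosphate pathway (adjusted p = 0.00926) and epididymis and testis markers (0.00502). Day and score side are close to confounded here.

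At day 4 the inguinal lists of the respiratory chain, the tricarboxylic acid cycle and fatty acid oxidation rose by camera at the preset correlation, with adjusted p = 0.184, adjusted p = 0.184 and adjusted p = 0.251 with an estimated correlation. Ucp1, Elovl3 and Cox7a1, a muscle and brown fat cytochrome oxidase subunit, rose over the thermogenic list alone. The respiratory chain had 47 of 49 positive (median 1.10). Of these, 0 rose over all genes and 19 over the list alone, among them the complex I genes Ndufs8 (1.76, SE 0.53) and Ndufv2 (1.48, SE 0.41), Uqcrc2 of complex III (1.63, SE 0.50) and Cox5b of complex IV (1.60, SE 0.44). The camera adjusted p was 1.15e-20 (adjusted p = 0.184 with an estimated correlation). The tricarboxylic acid cycle had 15 of 16 positive (median 1.34), with Fh1 (1.56, SE 0.38) and Mdh2 (1.52, SE 0.52) among 5 past the test over the list alone (adjusted p = 2.30e-10, adjusted p = 0.184 with an estimated correlation). Fatty acid oxidation had 19 of 20 positive (median 1.37), with Acadm (1.79, SE 0.60), Cpt2 (1.41, SE 0.40) and Acsl1 (1.60, SE 0.51) among 5 (adjusted p = 3.60e-08, adjusted p = 0.251 with an estimated correlation). Thermogenic genes had 15 of 16 positive (median 1.92, or 2.01 with the score), 9 past the test over the list alone (adjusted p = 2.24e-10, adjusted p = 0.243 with an estimated correlation). Ucp1 stood at 3538 ± 2598 CPM (n = 5), a log2 change of 3.95 (SE 0.87, list-alone adjusted p = 0.00328), above every day 0 library in 5 of 5. Elovl3 changed by 3.55 (SE 0.91) and Cidea by 1.77 (SE 0.64). With the score, members past the test over the list alone numbered 24 in the respiratory chain, 12 in the tricarboxylic acid cycle and 13 up and 1 down in fatty acid oxidation.

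Lipid synthesis lists also passed in iWAT at day 4. Triglyceride synthesis had 8 of 9 positive (median 0.81), with Agpat2 (1.68, SE 0.51) and Gpam (1.07, SE 0.41) among 4 past the test over the list alone (adjusted p = 2.55e-04, adjusted p = 0.251 with an estimated correlation). With the score Agpat2 alone passed, as Gpam and the other 2 reached 0.0566. By contrast 4 genes of pyruvate entry in place of 1, 5 of glycogen metabolism in place of 2, 3 of lipolysis in place of 1 and 2 of uptake in place of 1 then passed. De novo lipogenesis had 12 of 12 positive (0.62, 8.10e-05), peroxisomal genes 15 of 16 (0.67, 2.74e-04) and pyruvate entry 11 of 12 (1.03, 3.11e-04), each with an adjusted p = 0.266 with an estimated correlation. Glycerol metabolism had 4 of 4 positive (0.71, 0.00561, adjusted p = 0.213 with an estimated correlation), with Gpd1, which makes glycerol 3-phosphate, at 1.90 (SE 0.43). Further lists that passed were glycogen metabolism (13 of 17, 0.41, 0.0117, adjusted p = 0.311 with an estimated correlation), with Gys2 (2.89, SE 0.69) and Ppp1r3b, and sterol biosynthesis (14 of 18, 0.30, 0.0121, adjusted p = 0.258 with an estimated correlation). Lipolysis (7 of 9, 0.37, 0.01002, adjusted p = 0.413 with an estimated correlation) held G0s2, an inhibitor of lipolysis, at 1.95 (SE 0.58), and fatty acid uptake (6 of 8, 0.67, 0.0236, adjusted p = 0.426 with an estimated correlation) held Fabp3 at 2.74 (SE 0.79). Glycolysis (10 of 13, 0.95, 0.0294, adjusted p = 0.415 with an estimated correlation) and the pentose phosphate pathway (6 of 8, 0.78, 0.0330, adjusted p = 0.325 with an estimated correlation) completed the 15 lists that rose. Without iWAT553, glycolysis (adjusted p = 0.259), the pentose phosphate pathway (0.183), glycogen (0.0583), lipolysis (0.0999) and uptake (0.117) did not pass. Glycolysis was also lost without iWAT518 (0.0956) and iWAT548 (0.104) and iWAT551 (0.0681), and the pentose phosphate pathway without iWAT517 (0.0683) and iWAT522 (0.124) and iWAT550 (0.0620) and iWAT551 (0.0749). Uptake was lost without iWAT516 (0.0512) and iWAT517 (0.0683) and iWAT548 (0.0824) and iWAT550 (0.0781), and sterol biosynthesis without iWAT522 (0.0916).

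Of the 9 cell type lists, camera at the preset correlation passed 6 as lower in iWAT at day 4, along with cell cycle genes, and 0 with an estimated correlation. Over the list alone 0 of 21 cell cycle genes passed. Without the libraries high in epididymis and testis markers, 4 lists in place of 7 were lower. Macrophage markers had 12 of 12 negative (median -0.77, adjusted p = 2.81e-04, adjusted p = 0.254 with an estimated correlation), with the complement gene C1qb at -0.69 (SE 0.51). Lymphocyte markers had 11 of 12 (median -0.44, 0.00296, adjusted p = 0.427 with an estimated correlation). Their sum was 2223 ± 1459 CPM against 3201 ± 706 CPM at day 0. Single libraries ran from 902.3 to 4430 CPM at day 4 and from 2193 to 3749 CPM at day 0, so the days overlapped. Whether a varying share of other tissue in the pads underlies this was not tested. Fibroblast markers had 9 of 11 negative (median -0.95, 5.19e-04, adjusted p = 0.178 with an estimated correlation), with Col1a2 (-1.17, SE 0.34), Lum (-1.40, SE 0.42) and Thy1 (-1.47, SE 0.42) past the test over the list alone. Epithelial markers had 4 of 4 negative (median -1.58, 0.00167, adjusted p = 0.252 with an estimated correlation). Cell cycle genes had 19 of 21 (-0.47, 0.0117, adjusted p = 0.604 with an estimated correlation) negative, skeletal muscle markers 15 of 15 (-1.73, 0.00662, adjusted p = 0.587 with an estimated correlation) and nerve markers 3 of 4 (-0.79, 0.0452, adjusted p = 0.251 with an estimated correlation). On the high side of the score gap, fibroblast (adjusted p = 0.313), muscle (0.365) and nerve markers (0.585) did not pass. Muscle markers were also lost without iWAT517 (0.540) and iWAT522 (0.303) and iWAT551 (0.0681) and iWAT553 (0.0583), fibroblast markers without iWAT522 (0.0884), and lymphocyte markers without iWAT517 (0.0677) and iWAT553 (0.0703). Cell cycle genes were lost without iWAT516 (0.426) and iWAT517 (0.0771) and iWAT548 (0.0730) and iWAT553 (0.145). Nerve markers were lost without iWAT517 (0.133) and iWAT522 (0.148) and iWAT548 (0.126), iWAT551 (0.0526) and iWAT555 (0.0650), and with the score (0.0700).

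No gene passed over all genes in iWAT at day 4. In edgeR 0 were called, with 793 at an unadjusted p under 0.05, where 479 would arise by chance. DESeq2 called 37 higher and 6 lower, and voom 0. With the score 0 were called, and 4 without iWAT555, which held 3041 CPM of epididymis and testis markers. Between days 2 and 4, edgeR called 0, with 501 at an unadjusted p under 0.05, where 479 would arise by chance. DESeq2 called 2 higher, voom 0 and the score fit 0.

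**Figure D4:**
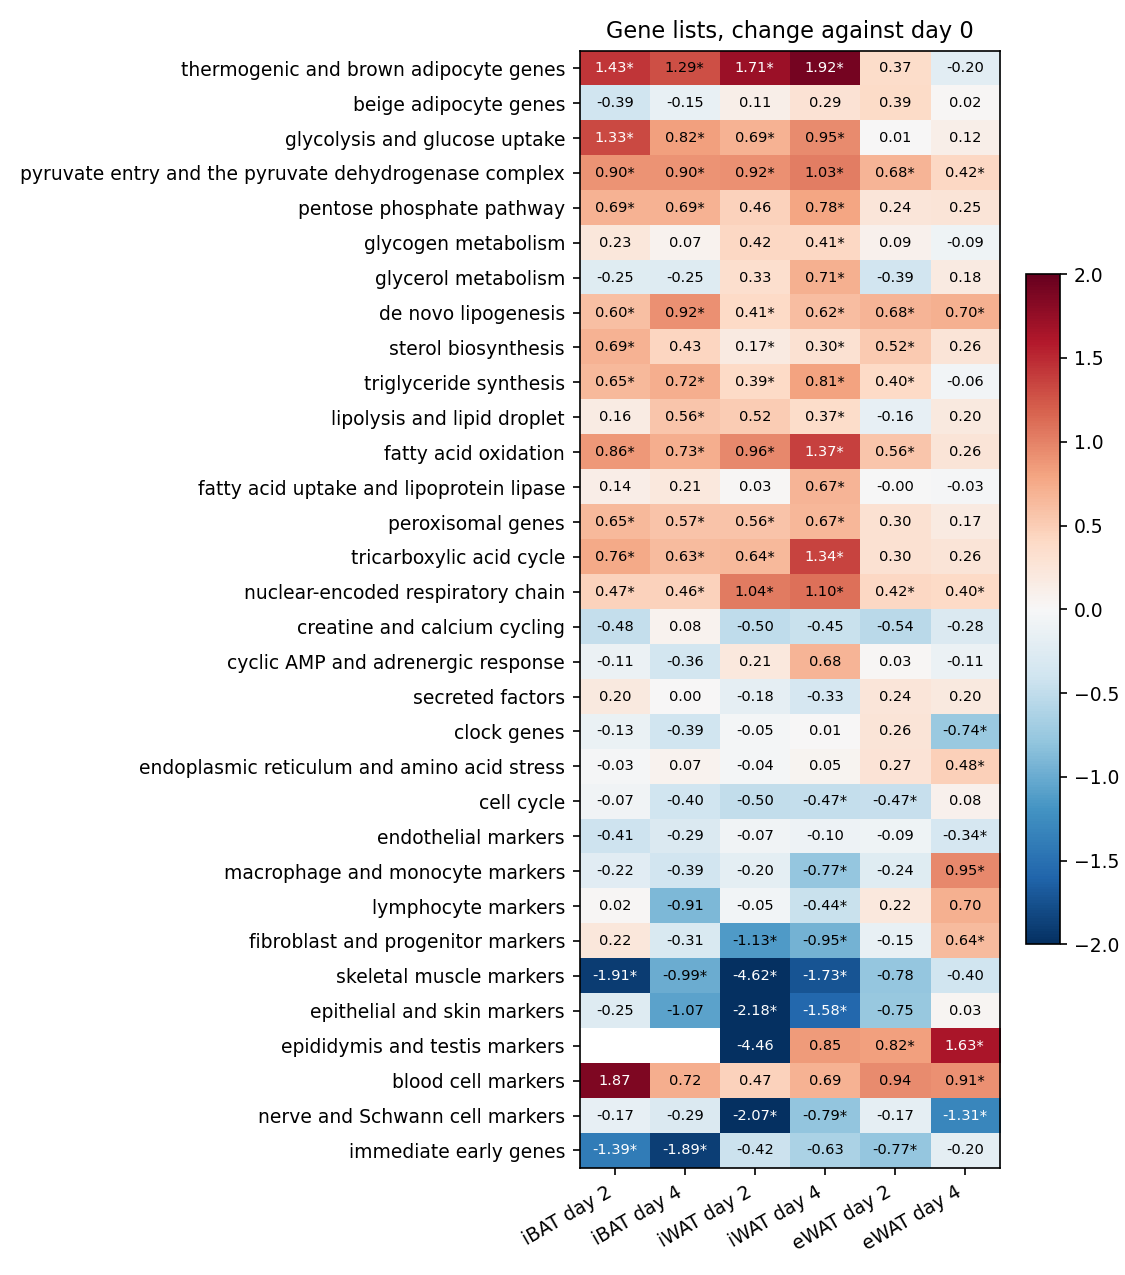
Median log2 change of each of the 32 gene lists against day 0 in the 3 depots at days 2 and 4, with a star for a camera adjusted p under 0.05 at the preset correlation. The respiratory chain list stands at 1.10 in iWAT at day 4 and 0.40 in eWAT at day 4.

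Epididymal fat was compared next, a depot with little thermogenic transcript at day 0. In eWAT at day 2 the lists for making lipids passed with positive medians at the preset correlation and not with an estimated one, with Fasn and the desaturase gene Scd1 the most abundant members, and thermogenic genes did not pass. De novo lipogenesis had 10 of 12 positive (median 0.68, adjusted p = 6.74e-05, adjusted p = 0.266 with an estimated correlation). Fasn stood at 5175 ± 1726 CPM (n = 3) against 1890 ± 1129 CPM, a log2 change of 1.45 (SE 0.62), and Scd1 at 30350 ± 7107 against 13060 ± 7609 CPM, 1.22 (SE 0.62), neither past the test alone. Sterol biosynthesis had 13 of 18 positive (0.52, 1.00e-03, adjusted p = 0.178 with an estimated correlation), triglyceride synthesis 9 of 9 (0.40, 0.00159, adjusted p = 0.266 with an estimated correlation) and pyruvate entry 10 of 12 (0.68, 0.00110, adjusted p = 0.178 with an estimated correlation). Fatty acid oxidation (17 of 20, 0.56, 0.00297, adjusted p = 0.400 with an estimated correlation) and the respiratory chain (41 of 49, 0.42, 3.11e-04, adjusted p = 0.317 with an estimated correlation) passed too. Immediate early genes had 12 of 12 negative (median -0.77, 3.11e-04, adjusted p = 0.266 with an estimated correlation), with Egr1 at -1.96 (SE 0.81), and cell cycle genes 13 of 16 (-0.47, 0.0309, adjusted p = 0.266 with an estimated correlation).

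Thermogenic genes in eWAT at day 2 had a median of 0.37 (adjusted p = 0.506) and Ucp1 a log2 change of -0.88 (SE 1.26). Epididymis and testis markers passed as well (9 of 12 positive, adjusted p = 0.0236, adjusted p = 0.473 with an estimated correlation; 0.313 with the score), while their summed level was 1139 ± 928 CPM at day 2 and 1298 ± 1572 CPM at day 0, with 2166 in eWAT532 and 3079 in eWAT516. Macrophage markers had a median of -0.24 and a mean of 0.05 (0.620). Without eWAT539, lipogenesis (adjusted p = 0.0579), triglyceride synthesis (0.104), pyruvate entry (0.103), fatty acid oxidation (0.117), the respiratory chain (0.282), cell cycle (0.0615) and epididymis markers (0.0589) did not pass, leaving 2 lists in place of 9. Without eWAT516, triglyceride synthesis (0.0663), fatty acid oxidation (0.110) and cell cycle (0.0909) were lost, and without eWAT518 sterol biosynthesis (0.113) and cell cycle (0.0516). Cell cycle genes were also lost without eWAT532 (0.457) and with the score (0.0671), and epididymis markers without eWAT517 (0.435) and eWAT532 (0.0998). Over 10043 genes edgeR called 0, with 106 at an unadjusted p under 0.05, fewer than the 502 that would arise by chance. DESeq2, voom and the score fit called 0 each.

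At day 4 in eWAT camera at the preset correlation passed 11 lists, and 0 with an estimated correlation. Macrophage, fibroblast, lipogenesis and respiratory chain lists were among those with positive medians, and endothelial, nerve and clock lists had negative ones. C1qa and C1qb, complement genes of tissue macrophages, rose over the list alone. C1qa went from 34.99 ± 11.89 to 130 ± 66.6 CPM (n = 3 and 3), by 1.90 (SE 0.50, list-alone adjusted p = 0.0262). C1qb went from 50.55 ± 21.97 to 183 ± 71.9 CPM, by 1.85 (SE 0.50, 0.0262), each above all day 0 libraries in 3 of 3. Over all genes neither passed, since the smallest edgeR adjusted p of any gene in this comparison was 0.9997. Chance alone would place all 3 day 4 libraries above all day 0 libraries for 5% of genes. Macrophage markers had 11 of 12 positive (median 0.95, or 1.24 with the score), at an adjusted p of 1.01e-06 (adjusted p = 0.251 with an estimated correlation). Their sum was 677 ± 289 CPM against 351 ± 122 CPM at day 0. Fibroblast markers had 11 of 11 positive (median 0.64, adjusted p = 7.18e-05, adjusted p = 0.178 with an estimated correlation), with Col1a1 at 1.05 (SE 0.98). Clock genes had 10 of 12 negative (median -0.74, 4.91e-04, adjusted p = 0.178 with an estimated correlation), with Nr1d2 (-0.99, SE 0.36), Per3 (-1.07, SE 0.48) and Dbp (-1.57, SE 0.61). Endothelial markers had 9 of 11 negative (median -0.34, 0.0239, adjusted p = 0.486 with an estimated correlation), and nerve markers 3 of 3 (0.0205, adjusted p = 0.250 with an estimated correlation).

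Lipogenesis stayed among the lists that passed in eWAT at day 4, with 11 of 12 positive (median 0.71, adjusted p = 3.81e-04, adjusted p = 0.305 with an estimated correlation). Pyruvate entry (9 of 12, 0.42, 0.0112, adjusted p = 0.250 with an estimated correlation) and the respiratory chain (38 of 49, 0.40, 2.55e-04, adjusted p = 0.310 with an estimated correlation) passed, as did genes of endoplasmic reticulum stress (9 of 14, 0.48, 0.0239, adjusted p = 0.266 with an estimated correlation), with the chaperone gene Calr at 1.12 (SE 0.59). Blood cell markers (4 of 4, 0.91, 0.0323, adjusted p = 0.251 with an estimated correlation) and epididymis and testis markers (11 of 12, 1.63, 6.24e-05, adjusted p = 0.251 with an estimated correlation) passed with positive medians. The latter summed to 4690 ± 7223 CPM, with 13030 in eWAT551. Thermogenic genes had a median of -0.20 (adjusted p = 0.681). The tricarboxylic acid cycle did not pass (0.25, 0.143) but did with the score (0.0205) and on the low side of the gap (0.00711). On that side, where 10 lists were higher and 3 lower, fatty acid oxidation passed as higher (0.00635) and epithelial markers as lower (0.0285). Without eWAT516, pyruvate entry (adjusted p = 0.140), lipogenesis (0.0836), stress (0.0509), blood (0.0987) and nerve markers (0.0578) did not pass. Without eWAT517, stress (0.0667), endothelial (0.237), epididymis (0.0605) and blood markers (0.110) did not. Each of these omissions left 7 lists in place of 11. Endothelial markers were lost without eWAT518 (0.133), eWAT551 (0.795) and on the low side of the score gap (0.0846), and stress (0.281) and nerve markers (0.160) without eWAT551. Without eWAT548, pyruvate entry (0.0614), the respiratory chain (0.120) and blood markers (0.0570) were lost, and without eWAT553 pyruvate entry (0.117) and blood markers (0.266).

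Single genes gave 0 edgeR calls in eWAT at day 4 over all genes. At an unadjusted p under 0.05 there were 277, fewer than the 502 that would arise by chance. DESeq2 called 1 higher and 3 lower, voom 0 and the score fit 0. From day 2 to day 4 edgeR again called 0, with 436 at an unadjusted p under 0.05, where 502 would arise by chance. DESeq2 called 1 lower, voom 0 and the score fit 0.

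**Figure D5:**
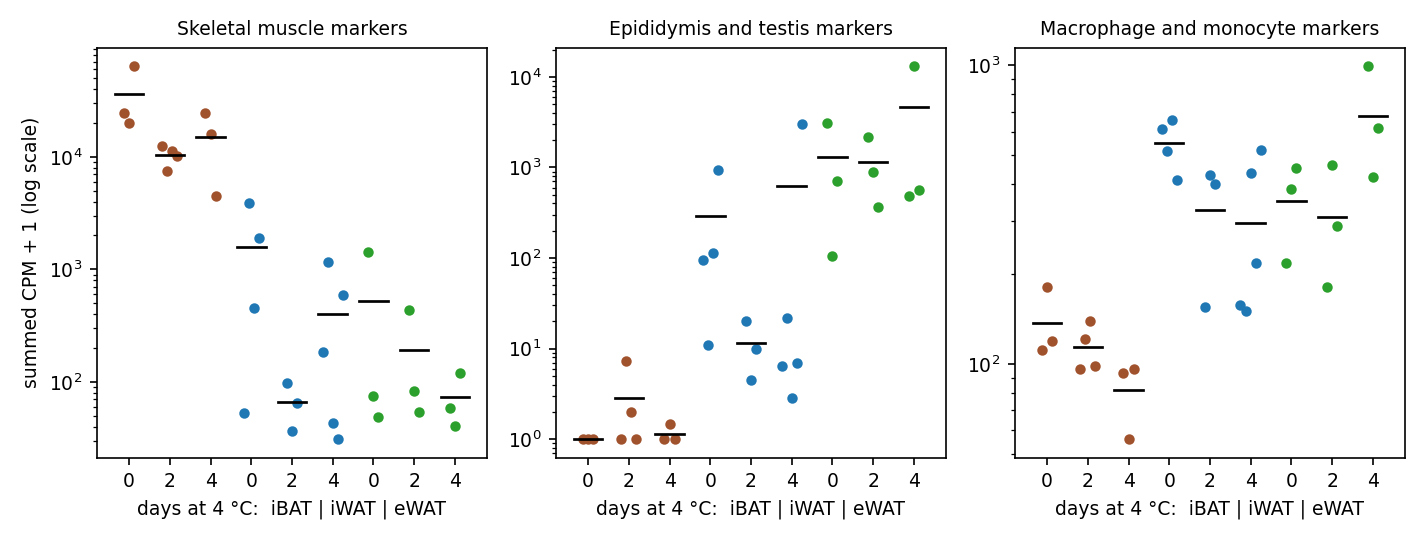
Summed CPM plus 1 (log axis) of skeletal muscle, epididymis and testis, and macrophage markers in each library by depot and day. Muscle markers average 36070 CPM in iBAT and 1584 CPM in iWAT at day 0, and macrophage markers 351 CPM at day 0 and 677 CPM at day 4 in eWAT.

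Whether the depots answered cold differently was tested on the difference of their day 4 changes. Ucp1 changed less in iBAT than in iWAT, by a log2 difference of -2.11 (SE 1.302, adjusted p = 0.853), and more in iWAT than in eWAT, by 2.56 (SE 1.34, adjusted p = 1.00). Neither difference passed. The difference for Lep was -2.92 (SE 1.11, adjusted p = 0.681), and for Cidea -1.69 (SE 0.87, adjusted p = 0.847), between iBAT and iWAT. In edgeR 0 of 10681 genes differed between iBAT and iWAT (648 at an unadjusted p under 0.05; 40 in DESeq2; 9 with the score, among them Ctsz, Tesc and Aldh1a1, and 0 with the score and the label number as a block), 0 between iBAT and eWAT (454; 25 in DESeq2; 0 with the score) and 0 between iWAT and eWAT (423; 7 in DESeq2; 0 with the score). Without iBAT548, 3 genes differed between iBAT and iWAT. A list that passed in 1 depot and not in another is therefore not shown to differ between them.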

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

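Of the tests weighed here, those of total count, transcript length, GC content, label number, library score and endothelial and other cell type markers were chosen only after the result was seen. A library was set apart where its gap to the nearest other library of its group passed Dixon's test in groups of 4 or 5. Of 76 values per group tested, 12 had such a library, where chance gives about 1 in 20, or 3.8.

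The first pattern is the axis along which libraries of each depot spread, on which iWAT522 had a score of -0.705 and the nearest other day 0 library 0.315. The score did not follow the total count (r = -0.033), and gene loadings did not follow transcript length (rho = -0.012) or GC content (rho = -0.045), which argues against these as the cause. Of 23 pairs of libraries with the same label number in 2 depots, 7 lay on the same side of the gap (30.4%). Independent sides would give 52.2%, so the side did not go with the label number. A shared number was not established to mean a shared animal, so this cannot decide on a property of the animal. A batch of library preparation could produce such an axis and stays open, since the labels name none, and no biological explanation was tested.

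The second pattern is the fall of skeletal muscle markers in iBAT after cold. Muscle carried along in the dissected pads is a candidate explanation: with the score removed, the 17 markers varied together within groups with a median pairwise r of 0.827, against a highest value of 0.44 in 1000 random lists. The most abundant of them stood at 8894 ± 6853 CPM at day 0 and 2307 ± 469 CPM at day 2 (Acta1) and at 5942 ± 4059 and 1586 ± 747 CPM (Tnnc2). The library axis was argued against, since the median log2 change with the score as a covariate was -1.9. A change in the cold of muscle gene expression in the depot itself stays open and was not tested. Muscle genes of the depot itself could also vary together within groups, and the random lists were matched on mean level only. The median r therefore does not tell these explanations apart.

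The third pattern is the rise of macrophage markers in eWAT at day 4. Over libraries, the mean log2 level of these markers was higher at day 4 by 0.97 (SE over libraries 0.44, 3 per group). With an estimated correlation camera passed 0 lists in this comparison. Of 10 splits of these libraries, 5 gave at least as many lists as the real one, the real one included, so chance stays open. Without the 3 libraries high in epididymis and testis markers, 1 of each time point, the median log2 change was 0.86. With the score as a covariate it was 1.24. These values argue against epididymis or testis tissue in some pads and against the axis as the whole cause. Other tissues in the pads were not tested. A lower share of adipocytes would raise markers of all other cell types alike, but endothelial markers had a median of -0.34 and macrophage markers 0.95. Within libraries, the mean log2 level of macrophage markers less that of endothelial markers was higher at day 4 by 1.39 (SE over libraries 0.23), and by at least 1.27 with any 1 library left out. This argues against a lower share of adipocytes as the whole cause. Nerve markers (2.25, SE 0.49, apart) and lymphocyte markers (0.52, SE 0.18) also lagged. A lower share stays open as a part, since fibroblast and blood markers moved with macrophage markers (0.16, SE 0.21, and 0.07, SE 0.38). More macrophages, or more of these transcripts in each, may underlie the rise, a hypothesis drawn from these data and not tested.

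The other libraries set apart are given without explanation. Epididymis and testis markers summed to 6.276 CPM in iBAT534 (nearest other 1.004), 937.6 in iWAT522 (111.2) and 3041 in iWAT555 (20.59). Blood cell markers summed to 485.6 CPM in iBAT539 (30.43), and nerve markers to 94.76 in iBAT535 (44.57). In iWAT522, endothelial markers summed to 1185 CPM (519.5), fibroblast markers to 3449 (2515), Hk2 stood at 517.96 CPM (171.54) and Adipoq at 5343 (1440). Epithelial markers summed to 273.4 CPM in iWAT555 (62.95), and Dio2 stood at 14.24 CPM in iWAT517 (1.967).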

How the results depend on the processing

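Fits with the score, on 1 side of its gap, without libraries with few features, without the library with most muscle markers and without libraries high in epididymis markers were chosen after seeing the data. Of 146 counts under other settings 112 stayed within 1.5 times and 34 moved, and of 165 with 1 library left out 142 stayed. Of 1752 values of named genes and lists under other settings 1469 kept their side of the threshold, 139 lost it and 144 gained it. With 1 library left out it was 1498, 186 and 3 of 1687. None changed direction past the threshold. At these depths and group sizes edgeR recovered 21% of simulated genes changed 4-fold in iBAT at day 2, so smaller changes stay below what single genes can show. Library size alone shifted the median gene by -0.28 (day 2) and -0.262 (day 4) in iBAT, -0.068 and -0.112 in iWAT, and -0.135 and -0.179 in eWAT.

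For iBAT at day 2 (13 genes in edgeR), library size alone left 1, no filter 40, DESeq2 306, only the 2 groups compared 22, the score 47, the low side of the gap 53, without the 2 libraries with few detected features 64, and without the library with most muscle markers 0. For iBAT at day 4 (0 in edgeR, 581 at an unadjusted p under 0.05), no filter gave 1, DESeq2 83, the score 19, the low side 19 and fits without libraries with few features 5. DESeq2 gave 111 in iWAT at day 2, 43 at day 4 and 2 between these days, 4 in eWAT at day 4 and 1 between days 2 and 4. Differences in day 4 change numbered 40 (iBAT and iWAT), 25 (iBAT and eWAT) and 7 (iWAT and eWAT) in DESeq2, and 9 for iBAT and iWAT with the score (0 with the score and the label number as a block). Between iWAT and eWAT at day 0 DESeq2 gave 1261 and the score 1302 (864 with the block). In iWAT, the high side of the gap gave 1 at day 4, and fits without libraries high in epididymis markers 66 genes and 9 lists at day 2. These day 2 fits leave out iWAT522, so day and score side are fully confounded in them. With an estimated correlation, 0 of 82 list calls by camera were past the test, 0 in each of the 6 comparisons. These camera runs differed only in the correlation setting, so the list calls rest on the preset value of 0.01. In counts simulated without correlation, the estimated setting still recovered 10, 10 and 5 of 10 raised lists in iBAT, iWAT and eWAT. How far members that vary together account for the loss in the real lists was not measured.

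With 1 library left out, counts ran from 0 to 3 (without iBAT532) in iBAT at day 2 and 0 to 4 (without iWAT555) in iWAT at day 4. They ran from 0 to 3 (without iBAT548) for the difference between iBAT and iWAT in day 4 change. At day 0 they ran from 1179 (without iBAT516) to 2264 (without iWAT522), 569 (without iBAT517) to 799 (without eWAT518) and 380 (without eWAT516) to 1225 (without iWAT522). Lists ran from 9 (without iWAT522) to 16 in iWAT at day 2, 2 (without eWAT539) to 12 in eWAT at day 2, and 7 (without eWAT516 or eWAT517) to 14 in eWAT at day 4.

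With the label number as a replicate block, 1434, 750 and 695 genes differed between depots at day 0 and 0, 0 and 0 in day 4 change (edgeR, 648, 454 and 423 at an unadjusted p under 0.05 without the block). Libraries with the same number correlated with a median r of -0.075 over 23 pairs, against 0.0305 over 82 others, so the numbers were not read as pairs.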

Other observations

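The tests of splits were planned, and the fits with the score beside them were chosen after seeing the data. The same libraries were split in other ways into groups of the same sizes, and the result of each split was set beside the real one. The planned bound was a share of splits under 0.05, with no allowance for the number of results tested. A share under it makes chance less likely without excluding it. At the preset correlation, other splits had a median of 5 and 4 lists in iBAT at days 2 and 4, 5.5 and 7 in iWAT, and 3 and 4 in eWAT.

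In iBAT at day 2 the share was under 0.05 for genes (13, highest other split 0, 1 of 35 splits as large). It was also under 0.05 for lists at the preset correlation, where another split came close (13, highest other 12, 1 of 35). For iBAT at day 4, 10 splits are too few for a share under 0.05 (genes 0, highest other 0, 10 of 10; lists 13, highest other 6, 1 of 10). Where the real count is 0, every split is as large by construction and the number of splits decides nothing. This holds between days 4 and 2 (0 genes, 35 of 35), where the split with iBAT548, iBAT535 and iBAT539, the high side of the score gap, called 1147 genes, which points to a structure of the samples. With the score as a covariate 0 were called.

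In iWAT at day 2, chance cannot be excluded for lists (14, highest other 15, 3 of 35). The count of 0 genes decides nothing (35 of 35), and the highest other was 219 with iWAT532, iWAT539 and iWAT522, all on the low side. At day 4 the 0 genes again decide nothing (100 of 100), and the split with iWAT550, iWAT551, iWAT553, iWAT516 and iWAT518, all on the high side, called 511. For lists at the preset correlation the share was under 0.05 (22, highest other 21, 1 of 100). Another split came close, and only 100 of 126 possible splits were tried, so chance is not excluded. With an estimated correlation 0 lists passed in any comparison. Between days 4 and 2 there were 0 genes (56 of 56), and the split with iWAT548, iWAT555 and the 3 day 2 libraries, the low side, called 382. These splits point to a structure of the samples, and with the score as a covariate 0 genes were called in each of these comparisons.

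In eWAT 10 splits are too few for a share under 0.05. At day 2 there were 0 genes (10 of 10), with 1520 in the split with eWAT532, eWAT538 and eWAT518, the high side, which points to a structure of the samples, and 9 lists (highest other 9, 2 of 10). At day 4 there were 0 genes (highest other 0, 10 of 10) and 11 lists (highest other 18, 5 of 10), and between days 4 and 2 there were 0 genes (highest other 0, 10 of 10).

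Between iBAT and iWAT at day 0 the share was under 0.05 (1926, highest other 1511, 1 of 35). The split with 1511 follows the score, but it differs from the real split only in the place of iWAT522. Depot and score are therefore not told apart in it. For iBAT and eWAT, 10 splits are too few (1029, highest other 0, 1 of 10). For iWAT and eWAT the count of genes cannot exclude chance (808, 2 of 35), since the split with iWAT516, iWAT517, iWAT518 and eWAT518, the high side, gave 810. That split also keeps most libraries with their own depot, so it still holds much of the depot difference. Summed lymphocyte markers did not overlap between these depots at day 0 (2193 to 3749 CPM in iWAT, 19.29 to 31.02 CPM in eWAT). With the score as a covariate the real split gave 1302. For the differences in day 4 change the real counts of 0, 0 and 0 decide nothing (highest others 0, 1 and 0, 30 of 30 each). Counts of 0 in this part are edgeR counts, whose values at an unadjusted p and by other tools stand in the results above.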
